A study of Mus musculus with 12 samples.

How the data were processed

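Total RNA from placentas of CD-1 mice on day 18 of pregnancy was hybridized to Affymetrix whole-transcript mouse gene arrays, after biotin labelling from 6 µg of RNA. The labels place 12 arrays in 4 groups of 3, by diet (24% or 6% protein) and infection (100 larvae per dose in 3 doses, or sham). Arrays of a group came from separate mice, so their spread is between animals. The values deposited by the authors are log2 signals per probe set, made with RMA in Affymetrix Expression Console per the submitters' processing notes, which give no versions. RMA corrects background, quantile normalizes the arrays and summarizes each probe set, which makes the distributions of the arrays alike and can shrink differences shared by most genes. The deposited array medians ran from 6.48 to 6.72.

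Of 41345 probe sets, 25341 had an annotated gene symbol, and the 16004 without one entered only an alternative that tested every probe set. The 1820 probe sets with several symbols were left out. A gene with several probe sets (1082 genes) was represented by the probe set with the highest mean, and the 19215 of 22180 genes with a mean log2 signal of at least 5 were tested. Group means were fitted with limma 3.58.1 in R 4.3.3 and empirical Bayes moderation (8 residual and 3.91 prior degrees of freedom). Contrasts gave the diet and infection effects averaged over the other factor, their interaction and the 4 simple effects. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, and differences are given as log2 ± SE. Positive diet differences mean higher on the protein-deficient diet, and positive infection differences mean higher in infected mice.

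The comparisons, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where the text says otherwise. The 43 gene lists cover placental and decidual cell types, blood and immune cells, and pathways of nutrition, stress, growth and immunity; they were tested with camera at a preset correlation of 0.01, with the correlation estimated per list, and with fry, and adjusted over the 42 lists with at least 5 measured genes. The list of Y-linked genes had too few and served as a measure of fetal sex. The error of a list mean comes from the means of the list in each array. For diet and infection, named genes were the 8 with the largest difference in each direction among those past the threshold, filled by smallest p where fewer passed. The 3 members with the smallest p of each called list, the insulin-like growth factor axis, Hsd11b1, Hsd11b2 and Slc38a2 were added, as were the 5 genes with the smallest p per direction for the interaction and 3 per direction for each simple effect. Provisional gene names, olfactory and vomeronasal receptors and small RNA genes were passed over. Of the growth factor axis, Igf2bp1, Igf2bp2 and H19 had no probe set with a single symbol.

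Exact permutation tests of array measures and list means swapped labels within the other factor (400 arrangements, two-sided). Permutation of list means, leaving out the 3 arrays of smallest signal SD, and the array SD as a covariate were added after the data were seen. The other alternatives were a replicate block, intensity trend with robust moderation, other filters, renormalization, other handling of probe sets, array weights, covariates for fetal sex and for decidual content, other thresholds, leaving out each array, and fitting only the 6 arrays compared. Genomic spans are those of the mouse reference annotation, from gene start to gene end, and are not transcript lengths. Splits of the arrays were drawn 100 at a time, the actual one included. The fit was tested on simulated data with 12 arrays and 200 changed genes per contrast.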

Results

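Placental gene expression was measured in pregnant CD-1 mice, an outbred strain, under protein deficiency and intestinal nematode infection in a factorial design. Mice ate a protein-sufficient diet with 24% protein or a protein-deficient diet with 6% protein from day 5 of pregnancy, and received either 100 infective larvae of Heligmosomoides bakeri, a nematode that lives in the mouse small intestine, or a sham dose on days 5, 10 and 15. Placentas were collected on day 18. Each of the 4 groups had 3 arrays, each from a different mouse, with the last placenta of each uterine horn of that mouse pooled into a single RNA sample. The deposited log2 signals ran from 2.25 to 13.96 over 41345 probe sets in 12 arrays, and 19215 genes were compared. Correlations between arrays over all probe sets lay between 0.924 and 0.992. Signal range differed between arrays within groups: the SD of the log2 signals was smallest in protein-deficient sham replicate 1 (2.12), protein-sufficient infected replicate 1 (2.17) and protein-sufficient sham replicate 3 (2.20), and reached 2.27 in the other arrays. The first principal component held 46.9% of the variance and set protein-deficient sham replicate 1 farthest from the others, with a score of -62.5. Neither the SD nor that component differed by diet (exact permutation p = 0.69 and 0.88, two-sided) or by infection (exact permutation p = 0.65 and 0.295). The mean signal of 3 Y-linked genes ran from 4.64 to 8.56 between arrays, as pools that differ in their mix of fetal sex would. It averaged 7.38 on the deficient and 6.11 on the sufficient diet (exact permutation p = 0.23). That gap of 1.27 was not told from chance with 6 arrays per diet, so an uneven mix of fetal sex by diet stays possible. By infection it averaged 6.79 in infected and 6.70 in sham arrays (exact permutation p = 0.955). The number of arrays limits the precision of every value below.

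The diet comparison asked how maternal protein deficiency altered the placenta, with the 6 protein-deficient arrays set against the 6 protein-sufficient arrays and infection balanced between them. Of the 16 leading genes by p, those with the lowest values on the protein-deficient diet relative to the protein-sufficient diet were Crabp1, which binds retinoic acid in the cytosol (log2 difference -1.37 ± 0.23 SE), Tfpi2, a serine protease inhibitor made by trophoblast (-0.89 ± 0.19), Pramel21 (-0.86 ± 0.16), the water channel Aqp1 (-0.85 ± 0.19) and the gap junction protein Gja1 (-0.74 ± 0.14). Tmem255a had the largest positive difference among the 16, at 1.15 ± 0.15 or 2.23-fold, followed by Slc38a3, a glutamine transporter (0.94 ± 0.21), Gprc5b (0.70 ± 0.14) and Pramel1 (0.60 ± 0.11). All 6 protein-deficient arrays lay on the same side of the protein-sufficient mean for each of these 9 genes, and for Tmem255a, Crabp1 and Aqp1 the arrays of the diets did not overlap. Their choice by small p favours such separation. The mean signal of Pramel21 was 4.87 on the deficient diet and 5.73 on the sufficient diet, close to the lowest level tested. No gene passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment. The lowest adjusted p was 0.136, for Tmem255a, and that of Crabp1 was 0.538. An unadjusted p under 0.05 was found for 992 genes, 577 higher and 415 lower, where chance alone would give 961. With arrays weighted by their residual spread, 818 genes passed for diet, 458 higher and 360 lower, but estimation of the weights stopped short of convergence. The median 95% confidence interval of a gene reached 1.20-fold either side of its estimate.

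The other leading genes by p, none past the adjusted threshold, included Ces2f, a carboxylesterase (0.49 ± 0.10), Grasp (0.59 ± 0.13), Gpr182, a receptor of endothelial cells (0.43 ± 0.09), and the orexin receptor Hcrtr1 (0.58 ± 0.13) on the higher side. On the lower side were Scnn1b, a subunit of the epithelial sodium channel (-0.50 ± 0.10), Plxdc2 (-0.63 ± 0.14) and the MHC class I gene H2-T24 (-0.43 ± 0.09). Across all genes, 40 were higher and 16 lower in every protein-deficient array than in every protein-sufficient array, 56 in both directions, where a chance share of 0.216% over both directions would give 41.6 genes.

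**Figure D1:**
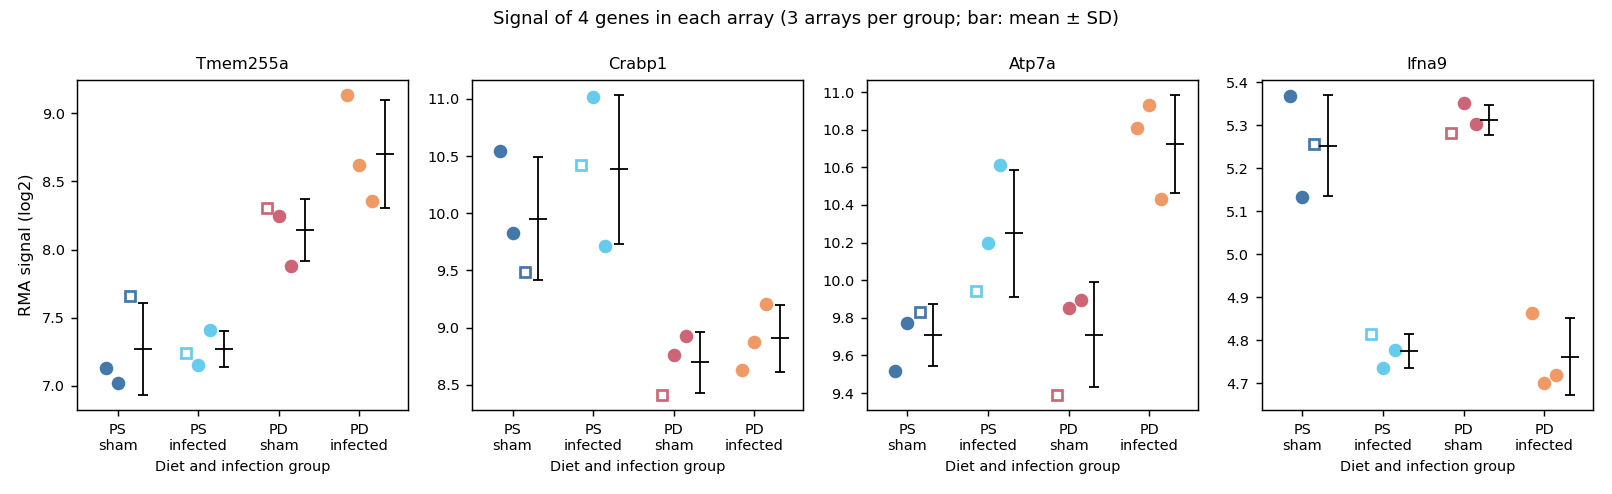
RMA signal (log2) of Tmem255a, Crabp1, Atp7a and Ifna9 in each of the 12 arrays, by diet (PS, protein sufficient; PD, protein deficient) and infection. Points are arrays, open squares are the 3 arrays with the smallest signal range, and bars are the mean and SD of 3 arrays. Tmem255a and Crabp1 separate by diet and Atp7a and Ifna9 by infection without overlap, although none of the 4 passed the adjusted threshold.

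Among gene groups, camera at its preset correlation called hormone and decidual lists lower and endothelial and erythroid lists higher on the protein-deficient diet. None of these calls held with the correlation estimated per list. Of 20 measured prolactin family hormones, which trophoblast and decidua secrete in pregnancy, 16 were lower, with a mean log2 difference of -0.21 ± 0.10. Prl3c1 differed by -1.11 ± 0.26, Prl7a2 by -0.50 ± 0.15 and Prl3a1 by -0.32 ± 0.10. Of 19 decidual stroma markers, 15 were lower (mean -0.28 ± 0.10), among them Hoxa10 (-0.52 ± 0.15) and the progesterone receptor Pgr (-0.62 ± 0.21); Prl3c1 is on that list too. Of 21 spongiotrophoblast and glycogen cell markers, 15 were lower (mean -0.12 ± 0.07), including Prl2a1 (-0.23 ± 0.08), Prl7a2 and Prl3a1. Of 18 endothelial markers, 16 were higher (mean 0.24 ± 0.11), with Robo4 at 0.56 ± 0.13, Tie1 at 0.40 ± 0.12 and Plvap, a protein of endothelial diaphragms, at 0.59 ± 0.21. Camera with its preset correlation called these 4 lists, with adjusted p = 2.8e-06 for prolactin hormones, 7.6e-05 for decidual stroma, 0.000676 for spongiotrophoblast and 2.66e-07 for endothelium. With an estimated correlation each of the 4 had an adjusted p = 0.425, and no call held. The median diet difference in sham and in infected mice was -0.10 and -0.28 for prolactin hormones, -0.33 and -0.27 for decidual stroma, -0.03 and -0.20 for spongiotrophoblast and 0.14 and 0.40 for endothelium.

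A further 4 lists were called for diet. Of 14 erythroid markers 12 were higher (mean 0.20 ± 0.10; adjusted p = 0.00124, and adjusted p = 0.621 with an estimated correlation), led by the embryonic globins Hbb-y (0.46 ± 0.16) and Hba-x (0.37 ± 0.18) and the heme synthesis enzyme Fech (0.38 ± 0.19). The mean signal of Hba-x was 5.01 on the sufficient and 5.38 on the deficient diet, close to the lowest level tested. Of 26 heat shock and unfolded protein response genes 22 were lower (mean -0.12 ± 0.09; adjusted p = 0.000384, and 0.961 with an estimated correlation), with Pdia6, an endoplasmic reticulum folding enzyme, at -0.24 ± 0.10, Sdf2l1 at -0.37 ± 0.16 and Hspa1b at -0.37 ± 0.16. Of 20 genes on the pregnancy-specific glycoprotein list, which also holds Ceacam genes, 12 were lower (mean -0.06 ± 0.07, camera adjusted p = 0.0262, and 0.961 with an estimated correlation). The median of that list was 0.007 in sham and -0.07 in infected mice. Its members with the smallest p were Ceacam genes: Ceacam11 at -0.23 ± 0.08, Ceacam12 at -0.27 ± 0.10 and Ceacam13 at -0.22 ± 0.10. Of 29 inflammatory cytokines and chemokines 19 were lower (mean -0.10 ± 0.05; adjusted p = 0.0277, and 0.459 with an estimated correlation), with the chemokine Cxcl12 at -0.39 ± 0.09, Tnf at -0.40 ± 0.15 and Csf1 at -0.27 ± 0.10. Leaving out protein-deficient sham replicate 1 ended the preset call of the erythroid list (adjusted p = 0.229, with Hba-x at 0.24) and of the heat shock list (adjusted p = 0.0694). For the glycoprotein and the cytokine lists 6 of the 12 arrays did so when left out. Adjusted p reached 0.278 without protein-sufficient sham replicate 3 and 0.234 without protein-deficient sham replicate 3. Ceacam13 moved to -0.15 without protein-deficient infected replicate 2. No member of any list passed over all genes, whereas 13 memberships in 9 lists passed when adjusted over the list alone. These were Prl3c1 in both its lists, Prl7a2, Prl3a1, Prl2c1 (-0.74 ± 0.24), Hoxa10, Robo4, Cxcl12, Slc38a3, Tfpi2, the lipoprotein receptor Scarb1 (0.54 ± 0.13), the transcription factor Klf2 (0.43 ± 0.11) and the death receptor Fas (0.40 ± 0.10). Prl2c1, Scarb1, Klf2 and Fas were named after their values were seen. An exact permutation of the list means per array called no list (lowest p = 0.03, for decidual stroma, and 0.7 adjusted). The smallest possible p was 0.005, with which a list alone could not pass after adjustment over 42 lists. That result therefore decides little.

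**Figure D2:**
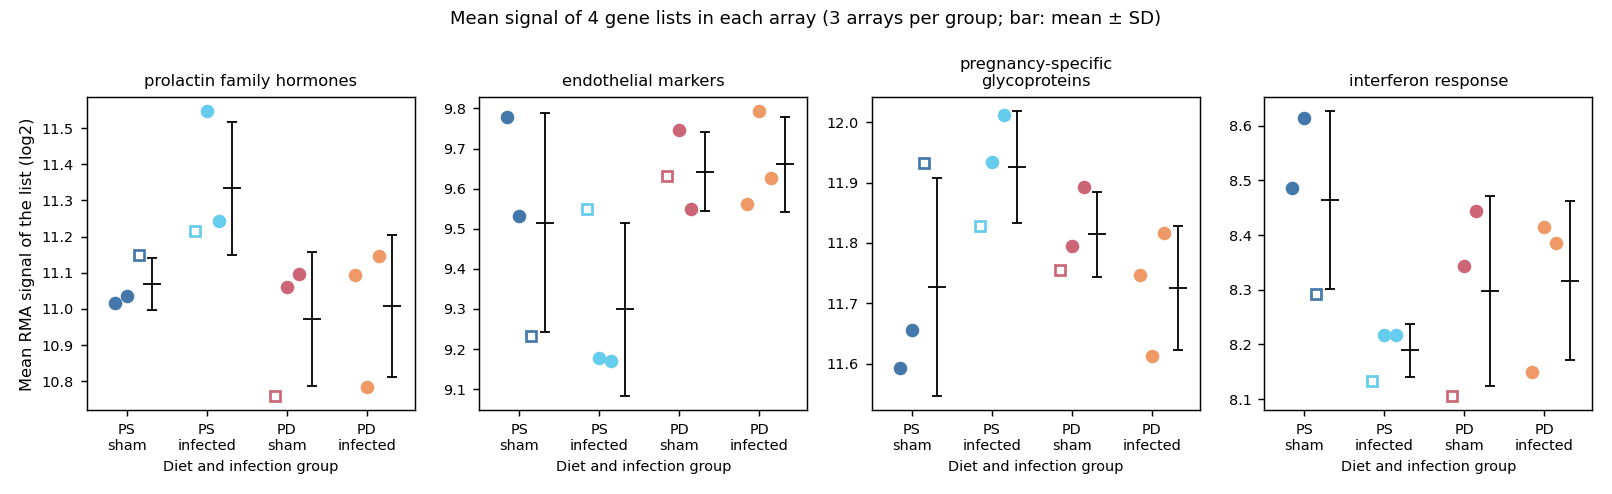
Mean RMA signal (log2) of the measured members of 4 gene lists in each array, by diet (PS, protein sufficient; PD, protein deficient) and infection. Points are arrays, open squares are the 3 arrays with the smallest signal range, and bars are the mean and SD of 3 arrays. The prolactin mean was lower by 0.21 and the endothelial mean higher by 0.24 on the protein-deficient diet, with arrays of the diets overlapping for all 4 lists.

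The infection comparison asked how the nematode, which stays in the gut, altered the placenta, with 6 infected arrays against 6 sham arrays and diet balanced between them. Infected placentas had higher signals of the copper transporter Atp7a (0.78 ± 0.14, or 1.71-fold), the calcium channel Itpr2 (0.56 ± 0.12), the cytoskeletal linkers Dst (0.55 ± 0.12) and Macf1 (0.42 ± 0.09), the ubiquitin ligase Mycbp2 (0.52 ± 0.11), Kidins220 (0.41 ± 0.08), Mga (0.41 ± 0.09) and the huntingtin gene Htt (0.41 ± 0.09). Signals were lower for Slc16a5, of the monocarboxylate transporter family (-0.99 ± 0.24), Pcp4l1 (-0.72 ± 0.12), the interferon alpha gene Ifna9 (-0.51 ± 0.08), the small GTPase Rhof (-0.50 ± 0.08), Rspo4, a Wnt pathway agonist (-0.36 ± 0.08), Tnfaip8l3 (-0.35 ± 0.08), Rnf166 (-0.32 ± 0.08) and Ankrd36 (-0.32 ± 0.08). All 6 infected arrays lay on the same side of the sham mean for each of these 16 genes, which their choice by small p favours. No gene passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, the lowest being 0.359 for Ifna9. The mean signal of Ifna9, 5.28 in sham and 4.77 in infected placentas, was close to the lowest level tested. There were 1365 genes at an unadjusted p under 0.05, 819 higher and 546 lower, against 961 by chance. With arrays weighted by their residual spread, 3745 genes passed for infection, 1728 higher and 2017 lower, but estimation of the weights stopped short of convergence. In every infected array compared with every sham array, 28 genes were higher and 33 lower, 61 in both directions, where chance would give 41.6 over both directions.

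The leading genes with higher signals in infected placentas were long. The 8 leading higher genes had a median genomic span of 192.1 kb and the 8 leading lower genes 23.3 kb, against 18.3 kb for the 19059 genes with a known span. Across those genes the infection difference correlated with log10 span (Pearson r = 0.24), whereas the diet difference did not (r = 0.003); genes are not independent replicates. With the genes ranked by span into 10 classes of equal size, the class of shortest genes had a mean infection difference of -0.09 and the class of longest genes 0.06. At an unadjusted p under 0.05, 241 of the longest genes were higher and 44 lower, and 44 of the shortest were higher and 100 lower.

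**Figure D3:**
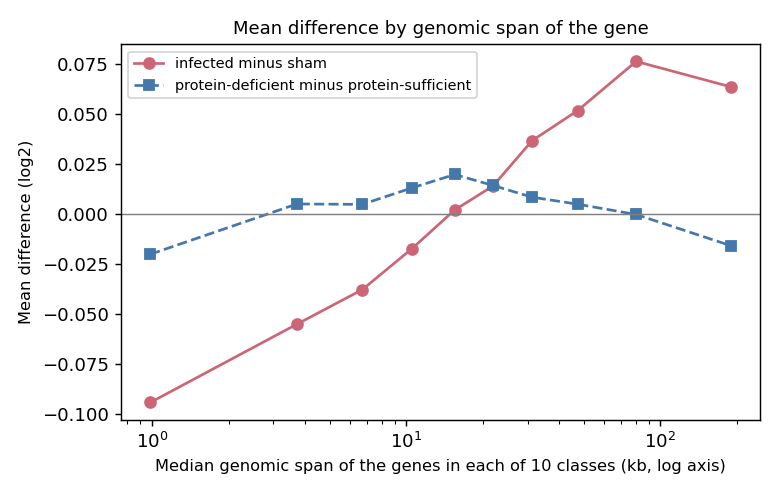
Mean log2 difference between infected and sham arrays, and between protein-deficient and protein-sufficient arrays, for genes ranked by genomic span into 10 classes of equal size, against the median span of each class in kb on a log axis. Each point is the mean over the genes of a class. The infection difference goes from -0.09 in the class of shortest genes to 0.08 and 0.06 in the classes of longest genes; the diet difference stays between -0.02 and 0.02.

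Camera with its preset correlation called 11 lists for infection, 7 higher and 4 lower, and 6 lists without protein-sufficient sham replicate 2. With an estimated correlation each of the 11 had an adjusted p = 0.874, and no call held. The infection difference also followed genomic span, and whether span accounts for any of these calls was not tested. Of 26 heat shock and unfolded protein response genes 23 were higher (mean 0.16 ± 0.09; adjusted p = 0.000201), with Pdia6 at 0.27 ± 0.10 and the chaperone Hyou1 at 0.32 ± 0.13, while the small heat shock protein Hspb1 was at -0.26 ± 0.10. Of 29 amino acid transporters 23 were higher (mean 0.15 ± 0.05, camera adjusted p = 0.00161). Among them were the cationic amino acid transporter Slc7a2 at 0.72 ± 0.16, Slc38a3 at 0.59 ± 0.21 (above the sham mean in 4 of 6 infected arrays) and Slc38a7 at 0.31 ± 0.12. The mean of that list was higher than the sham mean in all 6 infected arrays and gave the lowest p of any list in the exact permutation test, p = 0.015, which was 0.63 after adjustment. Of 31 genes of fatty acid uptake and lipid handling 21 were higher (mean 0.15 ± 0.07; adjusted p = 0.00666; median -0.004 on the sufficient and 0.28 on the deficient diet), with the cholesterol exporter Abca1 at 0.37 ± 0.09, the lipoprotein receptor Lrp1 at 0.57 ± 0.17 and Plin4 at 0.44 ± 0.13. Of 36 extracellular matrix genes 31 were higher (mean 0.14 ± 0.11; adjusted p = 0.0012; median 0.03 on the sufficient and 0.26 on the deficient diet), including the laminins Lamc1 (0.31 ± 0.11) and Lamb1 (0.30 ± 0.13) and the collagen Col4a1 (0.26 ± 0.12). The hypoxia response list (21 of 25 higher; adjusted p = 0.026; median 0.01 on the sufficient and 0.16 on the deficient diet) held Hk2 (0.33 ± 0.12), Slc2a3 (0.27 ± 0.11) and Kdm3a (0.29 ± 0.13). The glycogen metabolism list (15 of 19 higher; adjusted p = 0.0294) held Phka2 (0.38 ± 0.14), Phka1 (0.31 ± 0.15) and Gys1 (0.20 ± 0.12). The list of yolk sac endoderm and liver-type secreted proteins, markers of a neighbouring tissue, was also higher (19 of 21; mean 0.39 ± 0.53; adjusted p = 0.0287), with Cubn at 0.85 ± 0.45, Apob at 0.82 ± 0.47 and Amn at 0.44 ± 0.26, each above the sham mean in 4 of 6 infected arrays. Leaving out 1 array ended the preset call of the yolk sac list for 6 of the 12 arrays (adjusted p up to 0.491, without protein-sufficient sham replicate 1). It ended that of the hypoxia list for 5 and the glycogen list for 4 (adjusted p up to 0.146 and 0.236, without protein-deficient sham replicate 1). The matrix list lost its call without protein-deficient infected replicate 2 (adjusted p = 0.187). Gene values moved by over 1.5 times for Kdm3a (to 0.19), Phka1 (to 0.20) and Gys1 (to 0.12) without protein-deficient sham replicate 1. Apob moved to 0.54 without protein-sufficient sham replicate 1 and Amn to 0.29 without protein-deficient infected replicate 2.

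The interferon response, inflammatory cytokine, macrophage and ribosomal protein lists were the 4 called lower in infected placentas, each with an adjusted p = 0.874 with an estimated correlation. Neutrophil markers, which were not called, had a positive mean (0.10 ± 0.07; adjusted p = 0.083). Of 31 interferon response genes 24 were lower (mean -0.13 ± 0.08; adjusted p = 0.000445), with Cxcl10 at -0.37 ± 0.10, Ifit1 at -0.36 ± 0.13 and Rtp4 at -0.30 ± 0.12. Of 29 inflammatory cytokines and chemokines 22 were lower (mean -0.11 ± 0.05; adjusted p = 0.0163), with Ccl5 at -0.38 ± 0.17, Ccl3 at -0.36 ± 0.17 and Il1rn, an antagonist of interleukin signalling, at -0.21 ± 0.10. Of 21 macrophage markers 15 were lower (mean -0.12 ± 0.10; adjusted p = 0.026; median -0.20 on the sufficient and 0.01 on the deficient diet), with Folr2 at -0.33 ± 0.09, Pf4 at -0.46 ± 0.17 and the chemokine receptor Cx3cr1 at -0.37 ± 0.16. Of 43 ribosomal protein genes 33 were lower (mean -0.07 ± 0.07; adjusted p = 0.00666), with Rpl28 at -0.33 ± 0.13, Rpl32 at -0.29 ± 0.11 and Rpl7a at -0.26 ± 0.10. Leaving out 1 array ended the preset call of the macrophage list for 6 of the 12 arrays (adjusted p up to 0.178, without protein-deficient infected replicate 3) and of the ribosomal list for 3 (up to 0.129, without protein-deficient sham replicate 2). The cytokine list lost its call without protein-deficient sham replicate 1 (adjusted p = 0.0948), and Ccl5 moved to -0.25. No list member passed over all genes, whereas 8 passed when adjusted over the list alone: Slc7a2, Abca1, Cebpa (0.45 ± 0.11, a labyrinth trophoblast marker named after its value was seen) and 5 genes of the insulin-like growth factor axis.

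The insulin-like growth factor axis, which governs placental and fetal growth, was fixed for report whatever its values. With infection, the receptor genes Igf1r (0.29 ± 0.09), Igf2r (0.23 ± 0.08) and Insr (0.35 ± 0.11) and the protease Pappa2 (0.31 ± 0.10) were higher and the binding protein Igfbp6 was lower (-0.63 ± 0.19), each with adjusted p = 0.0461 in limma over the list alone and 0.684 over all genes. The ligand genes differed by -0.26 ± 0.14 for Igf1 and -0.01 ± 0.09 for Igf2. By diet, Igf2 differed by 0.19 ± 0.09, Igf1 by -0.18 ± 0.14 and Igfbp3 by 0.35 ± 0.18, and no member passed when adjusted over the list alone. Igf1 moved to -0.11, -0.08 and -0.09 by diet without protein-sufficient sham replicate 1, protein-sufficient infected replicate 1 or protein-deficient infected replicate 3, and Igfbp3 to 0.23 without protein-sufficient infected replicate 2. Hsd11b2, whose enzyme inactivates glucocorticoids, was at 0.05 ± 0.11 by diet and -0.28 ± 0.11 by infection, Hsd11b1 at -0.02 ± 0.14 and -0.28 ± 0.14, and the amino acid transporter Slc38a2 at 0.04 ± 0.08 and 0.14 ± 0.08. The infection difference of Hsd11b1 was -0.19 without protein-deficient sham replicate 2 and that of Slc38a2 0.09 without protein-sufficient sham replicate 3. Including those 3 and the genes not named here, the 23 genes fixed for report ranged from -0.21 to 0.47 by diet and from -0.63 to 0.35 by infection.

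The interaction asked whether infection acted differently on the protein-deficient diet than on the protein-sufficient diet, and positive values mean a larger infection difference on the deficient diet. The largest value among the leading genes was that of Psg19, a pregnancy-specific glycoprotein (-1.54 ± 0.44): its infection difference was 1.01 ± 0.31 on the sufficient diet and -0.54 ± 0.31 on the deficient diet. Psg18 (-0.94 ± 0.30), the germ cell gene Dazl (-0.79 ± 0.21), Fancd2os (-0.75 ± 0.22) and Gdpd2 (-0.74 ± 0.21) were also negative. On the positive side, Wfdc17 had 1.13 ± 0.29, Mal 1.10 ± 0.25, the neutrophil protein S100a8 0.92 ± 0.21, Pnma5 0.76 ± 0.15 and the acid phosphatase Acp5, made by macrophages, 0.68 ± 0.17. No gene passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, and the lowest adjusted p was 0.9995. An unadjusted p under 0.05 was found for 364 genes, 279 positive and 85 negative. Chance gives 961 on average, but the count varies widely between groupings. Of 100 random assignments of the arrays, the actual one included, 62 gave at least 364. With array weights 4 genes passed: Acp5, Pnma5, Zfp599 and the pseudogene Sycp1-ps1, of which Zfp599 and Sycp1-ps1 were named after their values were seen. The interval of a typical gene reached 1.44-fold either side.

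Among lists, camera called positive interactions for interferon, macrophage and growth factor genes and negative ones for placental hormone genes, but only at its preset correlation. Camera with its preset correlation called 16 lists, 10 positive and 6 negative, and none with an estimated correlation. The interaction also correlated with log10 genomic span across genes (r = 0.171), and a random assignment of the arrays reached 0.243. Whether span accounts for any of these calls was not tested. It called 8 after the arrays were quantile normalized again, 10 without protein-deficient sham replicate 3 and 9 without protein-deficient infected replicate 2. Of 31 interferon response genes 26 were positive (mean 0.29 ± 0.16; adjusted p = 0.599 with an estimated correlation): the median infection difference of the list was -0.29 on the sufficient diet and -0.02 on the deficient diet, and Bst2 (0.77 ± 0.30), Ifit1 (0.64 ± 0.26) and Gbp7 (0.59 ± 0.21) led it. Of 21 macrophage markers 17 were positive (mean 0.25 ± 0.21; adjusted p = 0.849 with an estimated correlation), led by the lysozyme Lyz2 (1.004 ± 0.40) and Mrc1 (0.63 ± 0.31), while Cd68 was at -0.35 ± 0.17. All 22 apoptosis and p53 target genes were positive (mean 0.23 ± 0.10; adjusted p = 0.599 with an estimated correlation), led by Pmaip1 (0.82 ± 0.35), Trp53inp1 (0.61 ± 0.27) and Eda2r (0.34 ± 0.20). Of 20 genes of the insulin-like growth factor axis 18 were positive (mean 0.23 ± 0.08; adjusted p = 0.599 with an estimated correlation), led by Irs1 (0.62 ± 0.20), Igf1r (0.48 ± 0.18) and Igfbp4 (0.53 ± 0.28). Of 20 genes on the pregnancy-specific glycoprotein list 16 were negative (mean -0.29 ± 0.14), with Psg22 at -1.78 ± 0.77. Of 20 prolactin hormones 16 were negative (mean -0.23 ± 0.19), with Prl8a1 at -1.10 ± 0.48 and Prl8a8 at -0.34 ± 0.16. Of 21 spongiotrophoblast markers 15 were negative (mean -0.23 ± 0.14), while Prl6a1 was positive at 0.75 ± 0.35. Each of these 3 lists had a camera adjusted p = 0.599 with an estimated correlation. Leaving out 1 array ended the preset call of the macrophage list for 7 of the 12 arrays (adjusted p up to 0.80, without protein-deficient infected replicate 2). The growth factor list lost its call without protein-deficient sham replicate 2 (adjusted p = 0.0594). Interactions moved by over 1.5 times for Mrc1 (to 0.36) and Pmaip1 (to 0.53) without protein-deficient infected replicate 2 and Psg22 (to -1.09) without protein-deficient infected replicate 1. Prl6a1 moved to 0.42 without protein-deficient sham replicate 1, Igfbp4 to 0.32 without protein-deficient sham replicate 3 and Eda2r to 0.22 without protein-sufficient infected replicate 2.

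The remaining positive lists were complement and acute phase (17 of 18 genes; adjusted p = 0.599 with an estimated correlation), with the acute phase gene Saa3 at 2.27 ± 0.88, and angiogenic factors and receptors (25 of 33; adjusted p = 0.599), with Nrp2 at 0.83 ± 0.31 and Met at 0.83 ± 0.40. Extracellular matrix (29 of 36; adjusted p = 0.834 with an estimated correlation) held Col18a1 at 0.48 ± 0.22, fatty acid uptake and lipid handling (25 of 31; adjusted p = 0.661) held Abcg1 at 0.63 ± 0.25 and Scarb1 at 0.60 ± 0.26, endothelial markers (14 of 18; adjusted p = 0.736) held Cldn5 at 0.62 ± 0.27, and immediate early genes (17 of 22; adjusted p = 0.661) held Klf2 at 0.49 ± 0.22 and Fosb at 0.68 ± 0.37. The remaining negative lists, again with the estimated correlation, were mast cell, basophil and eosinophil markers (8 of 13 genes; adjusted p = 0.613), with Tpsab1 at -0.56 ± 0.27, erythroid markers (11 of 14; adjusted p = 0.744), with Slc4a1 at -0.54 ± 0.57 (-0.12 without protein-deficient sham replicate 1 and -1.04 without protein-deficient sham replicate 3), and placental cathepsins (7 of 7; adjusted p = 0.661), with Ctsll3 at -0.41 ± 0.20. Leaving out 1 array ended the preset call of erythroid markers for 7 of the 12 arrays (adjusted p up to 0.92, without protein-deficient sham replicate 1). Immediate early genes lost it for 7, extracellular matrix for 4 and angiogenic factors for 2 (adjusted p up to 0.431, 0.668 and 0.234, each without protein-deficient infected replicate 2). Endothelial markers and cathepsins lost it for 5 arrays each (up to 0.314, without protein-sufficient sham replicate 1). Mast cell markers lost it for 4 and lipid handling for 3 (up to 0.571 and 0.109, without protein-deficient sham replicate 1). Complement lost it for 3 arrays (up to 0.332, without protein-deficient sham replicate 3). Fosb moved to 0.38 without protein-deficient sham replicate 1, Met to 0.55 without protein-deficient infected replicate 2 and Saa3 to 1.37 without protein-sufficient sham replicate 3. Col18a1 moved to 0.29 without protein-sufficient infected replicate 1 and Tpsab1 to -0.34 without protein-sufficient infected replicate 2. Over the lists, S100a8 was the 1 member that passed when adjusted over the list alone, against 0 over all genes.

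Infection was then compared with sham within each diet, 3 arrays against 3. On the protein-sufficient diet the leading genes were Pcp4l1 (-1.12 ± 0.17), Rhof (-0.68 ± 0.12) and Ifna9 (-0.48 ± 0.11) on the lower side and Samd12 (0.67 ± 0.17), the surrogate light chain gene Vpreb1 (0.52 ± 0.14) and Tdrkh (0.49 ± 0.13) on the higher side. On the protein-deficient diet they were Stra6, a retinol transporter (-0.75 ± 0.17), Ifna9 (-0.55 ± 0.11) and Tnfaip8l3 (-0.52 ± 0.12) on the lower side and Atp7a (1.01 ± 0.20), the transcription factor Cebpa (0.78 ± 0.16) and S100a8 (0.77 ± 0.15) on the higher side. For each of these genes the 3 infected and 3 sham arrays did not overlap, which chance gives for 10% of genes and choice by small p favours. The mean signal of Vpreb1 was 4.83 in sham and 5.35 in infected mice on the sufficient diet, close to the lowest level tested. No gene passed an adjusted p of 0.05 in limma on either diet, the lowest values being 0.433 for Pcp4l1 and 0.731 for Ifna9. Unadjusted p-values under 0.05 numbered 603 on the sufficient diet, 232 higher and 371 lower, and 1048 on the deficient diet, 729 higher and 319 lower, against 961 by chance. With array weights, whose estimation stopped short of convergence, 4179 genes passed on the sufficient diet and 1, Zfp599, on the deficient diet. Leaving out the 3 arrays of smallest signal range left 2 infected and 2 sham arrays on the sufficient diet. There 2 genes passed, the opioid peptide precursor Penk (-1.60 ± 0.16, against -1.08 in all arrays) and the sulfotransferase Chst5 (-0.93 ± 0.09, against -0.39). Both were named after their values were seen. With 1 array left out Chst5 ran from -0.70 to -0.23.

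Diet was likewise compared within sham and within infected mice. In sham mice Tmem255a (0.87 ± 0.22), the neuronal calcium sensor Hpca (0.63 ± 0.16) and Dazl (0.57 ± 0.15) were higher on the protein-deficient diet, and the estrogen sulfotransferase Sult1e1 (-0.84 ± 0.20), the macrophage scavenger receptor Msr1 (-0.61 ± 0.14) and Acp5 (-0.58 ± 0.12) were lower. In infected mice Tmem255a (1.43 ± 0.22), Gprc5b (1.20 ± 0.20) and Lacc1 (0.86 ± 0.17) were higher, and Crabp1 (-1.48 ± 0.33), Coch (-1.08 ± 0.24) and Nppc, the precursor of a natriuretic peptide (-1.05 ± 0.25), were lower. For each of these genes the 3 arrays of the diets did not overlap, which chance gives for 10% of genes and choice by small p favours. The mean signal of Dazl in sham mice was 5.28 on the sufficient and 5.85 on the deficient diet, close to the lowest level tested. No gene passed an adjusted p of 0.05 in limma in either set of mice, the lowest values being 0.9995 in sham mice, for Acp5, and 0.481 in infected mice, for Tmem255a. Unadjusted p-values under 0.05 numbered 471 in sham mice, 188 higher and 283 lower, and 859 in infected mice, 612 higher and 247 lower, against 961 by chance. With array weights 1244 genes passed in sham mice and 74 in infected mice. The median interval of a gene reached 1.29-fold either side in each of the 4 comparisons within a diet or an infection group.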

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

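The share of labyrinth tissue, the parts kept by the endothelial list and by the correlation with span, and the spread of the array slopes were tested only after values they rest on had been seen, and the long genes and the array weights were noticed in the data before they were tested. The jackknife SE as the margin for the parts kept was also added after those parts had been seen. The infection difference differed between the diets for 16 lists by camera's interaction test at the preset correlation. Adjusted p was 2.14e-05 for interferon response, 0.000395 for pregnancy-specific glycoproteins, 0.000455 for prolactin family hormones, 0.000634 for spongiotrophoblast and glycogen cell markers and 0.00117 for apoptosis and p53 targets. It was 0.00429 for extracellular matrix, 0.00432 for complement and acute phase and for angiogenic factors and receptors, 0.00579 for the insulin-like growth factor axis, 0.00791 for endothelial markers and 0.0122 for fatty acid uptake and lipid handling. It was 0.0153 for mast cell, basophil and eosinophil markers, 0.032 for erythroid markers, placental cathepsins and immediate early genes, and 0.0471 for macrophage markers. None of the 16 was called with an estimated correlation, where the lowest adjusted p was 0.599. Of 100 assignments of the 12 arrays to 4 groups, the actual one included, 13 called at least 16 lists and the highest other called 23, so chance was not excluded for that count. Outlying samples were not tested within the groups of 3 arrays; protein-deficient sham replicate 1 had the lowest score on the first principal component, -62.5.

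Camera at the preset correlation called placental hormone lists lower and the endothelial list higher on the protein-deficient diet. With an estimated correlation the calls of the prolactin, spongiotrophoblast and endothelial lists were lost (adjusted p = 0.425 each). Exact permutation called no list either (lowest adjusted p 0.7), but a list alone could not pass there after adjustment over 42 lists. A larger share of labyrinth, the exchange zone rich in vessels, against the hormone-making junctional zone may account for both; the labyrinth trophoblast list was higher by 0.031 ± 0.057, short of the 0.12 set as the bound, yet 2 SE reach above it, so this explanation stays open. With Y-linked signal as a covariate the endothelial list kept 1.17 of its difference (jackknife SE 0.198), above 0.5 by more than 2 SE. That argues against fetal sex as the main cause for the endothelial list. The prolactin list kept 1.05 (SE 0.402), but 2 SE reach below 0.5, so fetal sex stays open for that list. Without the 3 arrays of smallest signal range the endothelial list kept 0.979 (SE 0.464) and the prolactin list 0.791 (SE 0.383). For both, 2 SE reach below 0.5, so those arrays stay open for the endothelial and the hormone lists. A response to protein intake itself is the biological explanation and was not tested apart from these.

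The leading genes with higher signals in infected placentas were long, and the infection difference over all genes correlated with span, which RNA of better integrity or a labelling bias could give. The slope of signal on log10 genomic span was above the sham mean in 5 of 6 infected arrays (mean 0.032 in infected and -0.032 in sham arrays). That sham mean was pulled down by protein-deficient sham replicate 1, whose slope was the lowest at -0.162. The SD of the slopes within groups was 1.06 times the infected minus sham difference (jackknife SE 0.608), so a bias of arrays by length stays open. Slopes were higher in arrays of larger signal SD (Spearman r = 0.664), so this explanation overlaps with that of the arrays of smallest signal range. Without the 3 arrays of smallest signal range the correlation with span over all genes was 0.155, which is 0.647 of its value in all arrays (SE 0.398), so those arrays stay open too. Of 100 splits of infection labels, 9 gave a correlation of the difference with span at least as far from 0 as the actual 0.239, and the highest other was 0.253, so chance was not excluded. Genomic span stands in for transcript length, and infection as a biological cause was not tested apart from these. Whether span accounts for the infection differences or the interactions of gene lists or of the growth factor axis was not tested.

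Array weights brought 818 genes past the threshold for diet and 3745 for infection, where the unweighted fit had 0 and 0. The weights ran from 0.103 for protein-deficient sham replicate 1 to 7.98 for protein-sufficient sham replicate 1, and their estimation stopped short of its convergence tolerance. Of 100 splits of diet labels, the actual one included and each with weights of its own, 19 called at least 818 genes (highest other 6119). Such counts may therefore come from the weights alone. Of 100 such splits of infection labels, 2 called at least 3745 genes (highest other 4054). Splits of diet labels among the same arrays also went beyond 3745, up to 6119, so unstable weights stay open for infection too. Whether arrays of narrow range hide an infection effect stays open. The unweighted fit without those 3 arrays called 0 genes, but with fewer arrays that count decides little. The lowest adjusted p for infection fell from 0.359 to 0.0889 (0.118 with array SD as a covariate). On the sufficient diet, with 2 arrays left against 2, it fell from 0.433 to 0.038, with 2 genes called. On the deficient diet it fell from 0.731 to 0.125.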

How the results depend on the processing

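Leaving out the 3 arrays of smallest signal range, the array SD covariate and the permutation of list means were chosen after seeing the data. Replicate numbers gave no clear pairing of the samples, with correlations of same-numbered arrays from -0.54 to 0.62 (mean 0.104, against -0.047 for other pairs). Of 18 same-numbered pairs 10 lay over 0.1, and 6 of 12 arrays were closest to an array of their own number. A replicate block gave 0 genes in all 7 comparisons. All 7 counts of genes also stayed at 0 with an intensity trend and robust moderation, no filter, a mean of at least 6, both renormalizations, the mean of a gene's probe sets, every probe set, the sex, decidual and SD covariates, an adjusted p under 0.10, each array left out, and, for the simple effects, only the 6 arrays compared. With array weights they were 818 for diet, 3745 for infection, 4 for the interaction, 4179 and 1 for infection on the sufficient and deficient diets, and 1244 and 74 for diet in sham and infected mice. At an unadjusted p under 0.05 and at least 1.5-fold they were 94, 67, 193, 140, 163, 106 and 199 in that order. Without the 3 arrays of smallest range 2 genes passed for infection on the sufficient diet, from 2 arrays against 2, and 0 in the 6 other comparisons. The lists called (8, 11 and 16) fell to 0, 0 and 0 with an estimated correlation and to 0, 0 and 0 with fry's directional test (its test for members that move either way called 1 list for diet, prolactin hormones, adjusted p = 0.00222, and 0 for the others), and to 0 and 0 for diet and infection by exact permutation; these tests allow for correlated genes, which the preset correlation takes as small. Quantile normalization again gave 8 lists for the interaction, a change whose cause was not tested. With each array left out the lists ran from 6 to 12 for diet, from 6 (without protein-sufficient sham replicate 2) to 15 for infection and from 9 (without protein-deficient infected replicate 2) to 18 for the interaction, with 10 without protein-deficient sham replicate 3. The prolactin, endothelial and spongiotrophoblast lists kept their call for diet under each of the other alternatives, and the decidual list under all but its own mean as a covariate, which turned it (adjusted p = 0.668) by construction. Of 24 other alternatives, 13 ended the diet call of inflammatory cytokines, 9 that of pregnancy-specific glycoproteins, 2 that of erythroid markers and 1 that of heat shock genes. For infection 10 ended the call of the yolk sac list, 9 of glycogen metabolism, 8 each of hypoxia and macrophage markers, 5 of ribosomal proteins, 4 of inflammatory cytokines and 1 each of lipid handling and extracellular matrix. For the interaction 14 ended that of immediate early genes, 13 of erythroid, 12 of macrophage, 9 each of cathepsin and mast cell lists, 7 of lipid handling, 6 each of endothelial and complement lists, 5 of extracellular matrix, 4 of angiogenic factors and 1 of the insulin-like growth factor axis. Signs of named genes turned for values near 0: for diet, Hsd11b1 to 0.10 with array weights, 0.014 with the sex covariate and 0.15 without the 3 arrays, Slc38a2 to -0.015 with array weights and -0.018 without the 3 arrays, and Hsd11b2 to -0.031 with the sex covariate and -0.13 with the decidual covariate. With each array left out, the diet difference ran from -0.12 to 0.086 for Hsd11b1, from -0.025 to 0.10 for Hsd11b2 and from -0.013 to 0.072 for Slc38a2, and the infection difference of Igf2 from -0.072 to 0.026. The cause was not tested. On simulated data the fit recovered changes of main effects more often than of the interaction. At 1.5-fold it recovered 39 of 67 changes for diet and 0 of 67 for the interaction, and at 2-fold 61 and 27 of 67. The count of 0 genes for the interaction therefore leaves changes of such size open. The simulated noise was independent between genes and equal between arrays, unlike the arrays measured. Genes near the lowest levels tested have little signal over background.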

Other observations

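The splits of the arrays that count genes at an unadjusted p or correlate differences across genes were chosen after the gene counts had been seen. Several groups expected to matter in a protein-restricted placenta or a nematode infection were not called by camera. The amino acid response list of ATF4 targets, which cells induce when amino acids run short, had a mean diet difference of -0.01 ± 0.07 over 31 genes (camera adjusted p = 0.707). Amino acid transporters had 0.09 ± 0.05 by diet over 29 genes (adjusted p = 0.127), glucocorticoid-induced genes 0.07 ± 0.07 over 20 genes (adjusted p = 0.138), imprinted genes -0.05 ± 0.06 over 52 genes (adjusted p = 0.334) and cell cycle genes 0.05 ± 0.05 over 37 genes (adjusted p = 0.127). Type 2 immunity and alternative macrophage activation, the response that helminths drive in the gut, had a mean infection difference of -0.05 ± 0.07 over 22 genes (adjusted p = 0.276) and neutrophil markers 0.10 ± 0.07 over 19 genes (adjusted p = 0.083). T and B cell markers were at -0.09 ± 0.08 by infection (adjusted p = 0.083) and labyrinth trophoblast markers at 0.06 ± 0.06 (adjusted p = 0.316).

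Lists that camera did not call numbered 34 for diet, 31 for infection and 26 for the interaction. Their adjusted p ran from 0.0548 to 0.981 for diet, from 0.083 to 0.999 for infection and from 0.0744 to 0.987 for the interaction. The sign of the list mean and that of the test differed for 2, 5 and 6 of them, and for none of the called lists did mean, median and test differ in sign. Complement and acute phase genes had an infection difference of 0.04 ± 0.14 with a test pointing down (adjusted p = 0.757).

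Over all splits, chance was not excluded for the counts of genes at an unadjusted p or of lists in the unweighted fit, and the numbers of splits below include the actual one. At the adjusted threshold the actual count was 0 for diet, for infection and for the interaction, which all 100 splits reach whatever the data, so that comparison decides nothing; the highest other splits gave 1, 125 and 1. At an unadjusted p under 0.05, 24 of 100 splits gave at least the 992 genes of diet (highest other 5438), 13 the 1365 of infection (highest other 5420) and 62 the 364 of the interaction (highest other 4936). For lists, 67 of 100 splits called at least the 8 of diet (highest other 19) and 37 the 11 of infection (highest other 22). Infection labels split so that the 3 arrays of smallest range fell on the same side gave a median of 1424 genes at an unadjusted p under 0.05 in 22 splits, against 398 in the 77 others, and diet labels 1851 in 19 splits against 448.5 in 80, so the high counts point to the structure of those arrays. The actual labels put 2 of the 3 arrays on one side; among splits that do so, the actual one included, 2 of 78 gave at least the 1365 genes of infection (highest other 1420) and 7 of 81 the 992 of diet (highest other 1621), a comparison chosen after the counts had been seen. For the 4 simple effects the 10 splits of 6 arrays are too few for a share under 0.05, and the actual 0 genes are reached by all 10 whatever the data; the highest others gave 0, 0 and 0, and 1 for diet in infected mice. Across genes, infection differences on the sufficient and deficient diets correlated with r = 0.37, with the same sign in 63.2% of genes, and 27 of 100 splits reached that r (highest other 0.704). Diet differences in sham and infected mice correlated with r = 0.177, and 40 of 100 splits reached it (highest other 0.541).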
